A study of Gallus gallus with 12 samples.

How the data were processed

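Small RNA was sequenced from cells of chicken embryos. Per the labels' protocols, embryos received by electroporation a GFP expression vector together with constructs that delete the miR-302 of the chick or raise the level of human miR-302, and developed until Hamburger-Hamilton stages HH4-5. GFP-positive (GFP+) and GFP-negative (GFP−) cells were sorted into Trizol, RNA was extracted with a miRNeasy Mini column kit and Trizol-LS, and part of it was made into libraries with the NEXTflex Small RNA-Seq Kit and size selected on a gel. The first arm is called knockdown here because its samples carry a knocked-down label, although the protocol names a deletion. Each of the 4 groups (knockdown GFP+, knockdown GFP−, overexpression GFP+, overexpression GFP−) had 3 libraries, and replicate numbers were taken from the sample titles. The replicates are separately labelled samples with no stated separate embryos or cultures, so a p value measures the spread between these samples, which may be partly technical.

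Per the submitters' processing notes, the tools were FastQC 0.11.5, cutadapt and STAR 2.7.0f, with hg38 as the build. The chicken build, the counting tool and the source of the normalization factor are not given in the sources used here. The authors deposited 2 tables with all 12 libraries, one named as aligned to chicken and one as aligned to human, whose values are a normalized signal rather than counts. In every library, 100% of the values above 0 were whole multiples of 1 step within a tolerance of 0.001 reads, so the deposited signal is whole reads divided by 1 factor per library. Whole reads were recovered from it for the tests on counts. A further deposited sheet holds the authors' GFP+ to GFP− ratio for 5 members of the miR-302/miR-367 family. Each table lists hairpins and mature arms, and no mature arm was above 0, so arms could not be compared and all values are for hairpins. Hairpins with near-identical copies (let-7a, miR-9, miR-92, miR-122, miR-124, miR-218 and miR-1a) can share reads, and how such reads were assigned is not given in the sources used here. Both tables come from the same 12 libraries, so they are not independent evidence.

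The chicken-aligned table had 912 hairpin entries. Of these, 61 repeated an earlier name and were dropped, 8 of them above 0, which left 851. The human-aligned table had 1921 hairpin entries, of which 5 repeated a name, 3 of them above 0, which left 1916. Hairpins with a mean of at least 10 normalized reads over the 12 libraries were tested, which gave 132 in the chicken-aligned and 114 in the human-aligned table. Of the 851 chicken names, 780 were matched by symbol in the RefSeq gene table, which gave chromosomes but no coordinates.

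The groups, tests, lists and most alternatives were chosen before the data were examined. Values were taken to log2 with a pseudocount of 1 and fitted with limma 3.58.1 (R 4.3.3; 4 group means, empirical Bayes with a trend). The contrasts, tested two-sided, were GFP+ against GFP− in each arm, the difference of these 2 GFP effects, and GFP− cells of the overexpression arm against those of the knockdown arm. A hairpin was called at an adjusted p (limma, Benjamini-Hochberg) under 0.05. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads of the same hairpins. The sum of all miR-302 and miR-367 hairpins was compared by an exact two-sided permutation test on log2 values, for which 3 libraries against 3 allow no p below 0.1.

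The 12 lists, matched by family number, were the miR-302/miR-367 family (miR-302, miR-367), miR-302 seed relatives (miR-372, miR-373, miR-427, miR-428, miR-430, miR-520), the miR-17/miR-92/miR-106/miR-25 families (miR-17, miR-18, miR-19, miR-20, miR-25, miR-92, miR-93, miR-106, miR-363), let-7/miR-98, neural (miR-7, miR-9, miR-124, miR-128, miR-137, miR-153, miR-218, miR-219), muscle and cardiac (miR-1, miR-133, miR-206, miR-208, miR-499), blood and endothelium (miR-126, miR-142, miR-144, miR-150, miR-155, miR-223, miR-451, miR-486), endoderm and liver (miR-122, miR-192, miR-194, miR-215, miR-375), epithelium (miR-141, miR-200, miR-203, miR-205, miR-429), mesenchyme (miR-140, miR-143, miR-145, miR-199, miR-214), Hox-cluster (miR-10, miR-196, miR-615), and stress and inflammation (miR-21, miR-34, miR-132, miR-146, miR-147, miR-210, miR-212). Lists with at least 3 tested members were tested with fry, which asks whether members move on balance one way, whatever the other hairpins do. They were also tested with camera, which sets members against the other hairpins, at a preset correlation of 0.01 and at an estimated correlation. Hairpins were named by a fixed rule. It took every miR-302/miR-367 hairpin and miR-1811, and up to 10 rising and 10 falling calls with the largest folds among those whose GFP+ libraries all lay on one side of the GFP− libraries. It added the 5 smallest p where fewer than 5 passed, up to 4 members per list with the highest mean, and the 5 most abundant hairpins. For the other 2 contrasts it took the 5 calls with the largest folds.

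The alternatives chosen at that point were other pseudocounts, no filter or a minimum mean of 50, TMM and median-of-ratios scaling, no trend, a fit of the compared groups only, the replicate number as a block, edgeR, DESeq2, and leaving out each library in turn. Thinning every library to the shallowest one and a pseudocount worth 1 read in the shallowest library were added after seeing the data. In the chicken-aligned table the residuals of GFP+ and GFP− libraries with the same arm and number correlated at r = 0.15, 0.38 and 0.14 in the knockdown arm and 0.21, 0.32 and 0.11 in the overexpression arm. The numbers were therefore taken to pair samples in the blocked and paired tests, while the main limma fits left them unpaired. Knockdown replicate 1 correlated better with number 3 (0.19) than with its own, and the other 5 best with their own. In the human-aligned table of the same libraries r ranged from −0.14 to 0.36, and only knockdown replicate 1 and overexpression replicate 2 correlated best with their own number. Blocked values are given for both tables where they change a call. Methods were tested on simulated data with the observed depths. With no true change, limma made a mean of 2.6 (chicken) and 4.12 (human) falling calls per run in the overexpression contrast, up to 7 and 11, where edgeR made 0.1 and 0.04 calls in all. In the knockdown contrast limma made 0. With known folds put into part of the hairpins, limma made 4.06 (chicken) and 6.3 (human) false calls per run in the overexpression contrast. There edgeR made 0.68 and 0.66. The simulation used 1 common dispersion for all hairpins of a table. Simulated rises of 3 on the log2 scale were recovered by limma at 79.2% to 83.6% and falls of that size at 41.2% and 43.6% in the knockdown arm, but rises of 1 on that scale at 2.4% to 7.6%. Falls of 1 in the knockdown arm were recovered by limma at 0.8% (chicken) and 1.6% (human) and by edgeR at 10.8% and 26%. Intervals and limits for reads cover counting error only.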

Results

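The data were small RNA reads from GFP+ and GFP− cells sorted from chicken embryos labelled as having miR-302 knocked down or overexpressed, with 3 libraries in each of 4 groups. Depth differed strongly between groups. In the chicken-aligned table, hairpins held 49276, 82211 and 80407 reads in the knockdown GFP+ libraries 1 to 3, and 325485, 277633 and 435716 in the knockdown GFP− libraries. The overexpression GFP+ libraries held 3856, 1292 and 1789 reads, and the overexpression GFP− libraries 7546, 52653 and 277637. The human-aligned table had between 518 reads (overexpression GFP+ replicate 2) and 254098 (knockdown GFP− replicate 3). A single read was therefore worth 6.68, 24.4 and 15.9 normalized reads in the overexpression GFP+ libraries of the chicken-aligned table, and 0.1 to 0.158 in the knockdown GFP− libraries. Where a hairpin had no read, 3 reads set the upper limit. In the shallowest library it was 73.1 normalized reads in the chicken-aligned and 116.0 in the human-aligned table. All levels below are deposited normalized reads, given as mean ± SD with n = 3 per group, and named hairpins are gga- (chicken) or hsa- (human) precursors. An hsa- name marks the hairpin that a read was aligned to, not its origin. Knockdown GFP− replicate 1, in the arm with the construct against chick miR-302, held 62306 hsa-mir-302b reads. Reads on human hairpins can thus be of chick origin.

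The miRNAs with the highest means over the 12 libraries of the chicken-aligned table came from 2 families. gga-mir-92-2, of the proliferation-linked miR-17/miR-92 families, made up 17.06% of the summed means and gga-mir-92-1 7.46%. The miR-302/miR-367 family, known for its expression in embryonic stem cells and early embryos, contributed gga-mir-302b (12.7%), gga-mir-302d (10.84%) and gga-mir-302a (8.84%). In the human-aligned table hsa-mir-302b (21.05%) and hsa-mir-92a-2 (20.98%) led, before hsa-mir-92a-1, hsa-mir-21 and hsa-mir-30d. The order differed between groups. gga-mir-302b was above gga-mir-92-2 in knockdown GFP− cells (7437.7 against 6683.0) and below it in overexpression GFP+ cells (2280.8 against 6002.2). hsa-mir-302b was above hsa-mir-92a-2 in the knockdown arm only.

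The first comparison asked how the targeted family differed between GFP+ and GFP− cells of the knockdown arm. In GFP+ cells gga-mir-302b stood at 5555.7 ± 998.9 against 7437.7 ± 1067.3 in GFP− cells (log2 fold −0.43), gga-mir-302d at 4914.3 ± 739.4 against 6129.4 ± 637.0 (−0.33) and gga-mir-302a at 4163.4 ± 1179.2 against 5201.1 ± 355.0 (−0.36). gga-mir-302c, at 1129.4 ± 468.4 against 1140.4 ± 184.3 (−0.10), and gga-mir-367, at 25.8 ± 10.2 against 28.6 ± 8.6 (−0.18), turned to 0.09 and 0.01 with TMM scaling. gga-mir-1811, whose gene is on chromosome 4 with those of the family, had 77.4 ± 31.1 against 66.4 ± 17.4. Of the 5 family members tested none was called by limma, over all hairpins or adjusted over the list alone, by edgeR or by DESeq2. Falls of this size would mostly be missed, as limma recovered 0.8% and edgeR 10.8% of simulated falls of 1 on the log2 scale here. The smallest limma adjusted p was 0.65 (gga-mir-302b). fry gave the list an adjusted p of 0.634. The family summed to 15788.7 ± 3383.7 in GFP+ and 19937.2 ± 2222.3 in GFP− cells, a ratio of 0.792 and a log2 difference of −0.355 (SE 0.21, exact permutation p = 0.2). All 3 same-number pairs were lower in GFP+ cells (paired SE 0.12, exact sign-flip p = 0.25, the smallest that 3 pairs allow). Without knockdown GFP+ replicate 2 the difference was −0.162.

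For human hairpins the knockdown arm gave a summed family ratio of 0.76 (6174.2 ± 1575.2 against 8119.3 ± 1434.4, log2 difference −0.410, exact permutation p = 0.3). It was lower in GFP+ cells in all 3 pairs (paired SE 0.07, exact sign-flip p = 0.25). hsa-mir-302b carried most of it, at 5189.2 ± 1218.2 against 7054.0 ± 1261.4 (−0.45). hsa-mir-302a stood at 108.8 ± 37.6 against 114.5 ± 20.9, hsa-mir-302d at 180.9 ± 41.1 against 227.4 ± 54.7, hsa-mir-302c at 637.3 ± 304.9 against 679.8 ± 89.4 and hsa-mir-302e at 47.5 ± 9.5 against 34.2 ± 7.4. No member of the 5 tested was called by limma, over all hairpins or adjusted over the list alone, and fry gave the list an adjusted p of 0.759. Without knockdown GFP− replicate 1 the summed difference was −0.269. The authors' ratios for this arm, 0.747 (miR-302b), 0.99 (miR-302c), 0.8 (miR-302a) and 0.802 (miR-302d), equal the ratios of group means in the chicken-aligned table, while their 1.0 for miR-367 compares with 0.903.

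**Figure D1:**
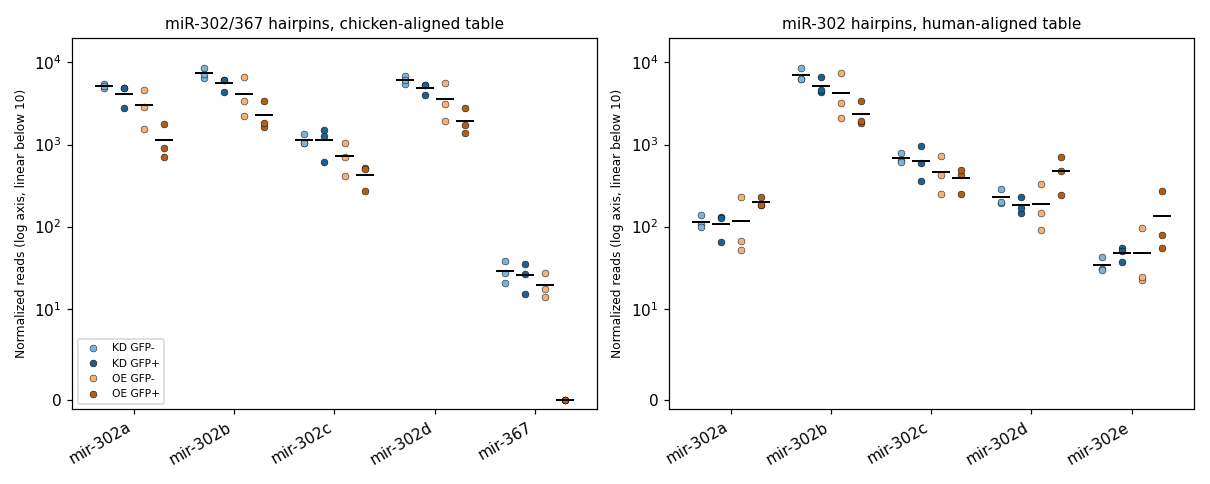
Normalized reads (vertical axis, logarithmic above 10 and linear below) of each miR-302/miR-367 hairpin in the chicken-aligned (left) and human-aligned (right) tables, with 1 point per library, a line at the mean of 3 libraries, and colours for the knockdown (KD) and overexpression (OE) groups. In the overexpression arm the mean of hsa-mir-302d is higher in GFP+ cells (472.1 against 189.1), while that of gga-mir-302a is lower (1140.9 against 2996.9).

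The same question in the overexpression arm gave lower values of the chicken hairpins, and higher values of some human hairpins, in GFP+ cells. gga-mir-302a stood at 1140.9 ± 581.6 against 2996.9 ± 1521.5, gga-mir-302b at 2280.8 ± 963.6 against 4116.9 ± 2328.4 (log2 fold −0.78) and gga-mir-302d at 1963.0 ± 707.8 against 3544.4 ± 1854.9 (−0.78). gga-mir-367 had no read in GFP+ cells, where 4.9 were expected from the GFP− level of 19.5 ± 7.0, which makes it at least 1.65-fold lower (floor of 3 reads over the group). gga-mir-302c had 431.1 ± 136.1 against 721.9 ± 310.9 and gga-mir-1811 35.7 ± 11.5 against 43.4 ± 20.4. Of the 5 members gga-mir-302a (fell by 1.37 on the log2 scale, limma adjusted p = 0.0378) and gga-mir-367 (0.000687) were called, as they were when adjusted over the list alone. fry gave the family a fall with an adjusted p of 0.00252 (camera adjusted p = 0.436 with an estimated correlation). The median log2 fold of the list was −0.78 with gga-mir-367 as fitted or at its bound, and the mean −1.59 or −0.87. All tested chicken hairpins had a median log2 fold of −0.67 in this contrast, so fry by itself cannot show a fall particular to the family. Camera with the preset correlation gave the family an adjusted p of 0.0912. As a percent of the summed values of each library, the family took 16, 27 and 18 in GFP+ replicates 1, 2 and 3. The GFP− replicates had 21, 42 and 25, so each pair was lower in GFP+ cells, although the groups overlapped. A fall particular to the family was thus neither shown nor excluded. With replicate number as a block, limma also called gga-mir-302b and gga-mir-302d (adjusted p = 0.00424 for both, with ranges over the alternatives of 0.00424 to 0.458 and 0.00424 to 0.369).

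The gga-mir-302a call was not stable, since the GFP+ and GFP− libraries overlapped and its limma adjusted p ranged from 0.00175 to 0.155 over the alternatives. It was 0.0934 without overexpression GFP+ replicate 1, 0.0838 without GFP+ replicate 3, 0.118 without GFP− replicate 2 and 0.111 without GFP− replicate 3 (limma adjusted p), and TMM scaling gave 0.059. Leaving out GFP− replicate 1 brought gga-mir-302b (0.0476) and gga-mir-302d (0.028) under the limma adjusted p threshold. DESeq2 gave gga-mir-367 an adjusted p of 0.0986 against a range over the alternatives of 0.000125 to 0.42. The chicken family summed to 5815.8 ± 2338.6 against 11399.5 ± 5990.4, a ratio of 0.51 and a log2 difference of −0.909 (SE 0.55, exact permutation p = 0.2), which was −0.514 without GFP− replicate 2. Each of the 3 pairs was lower in GFP+ cells (−0.63, −1.09 and −1.01, paired SE 0.14, exact sign-flip p = 0.25).

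For human hairpins of the family, hsa-mir-302d had 472.1 ± 225.7 against 189.1 ± 122.5 normalized reads in the overexpression arm (log2 fold 1.39, limma adjusted p = 0.0739), hsa-mir-302a 198.8 against 116.4 (1.08, SE 0.52, 0.169) and hsa-mir-302e 134.8 ± 118.2 against 47.8 ± 42.6 (1.47, 0.169). hsa-mir-302b, also abundant in the knockdown arm, had 2363.8 ± 867.4 against 4247.4 ± 2834.5 (−0.70) and hsa-mir-302c 390.7 ± 124.8 against 467.8 ± 238.8 (−0.18). No member of the 5 was called by limma, over all hairpins or adjusted over the list alone, and fry gave an adjusted p of 0.337. Without overexpression GFP− replicate 2 limma called hsa-mir-302a (adjusted p = 0.0103, range over the alternatives 0.0103 to 0.654) and hsa-mir-302d (0.0141, range 0.0141 to 0.329), and without GFP+ replicate 1 it called hsa-mir-302d (0.0242). With the block it called hsa-mir-302d (0.0188) and the fall of hsa-mir-302b (0.0429, range 0.0429 to 0.724). The family summed to 3560.2 ± 1267.8 against 5072.3 ± 3335.7 (ratio 0.702, log2 difference −0.366, exact permutation p = 0.7), and the difference turned to 0.136 without GFP− replicate 2 and was −0.775 without GFP− replicate 1, −0.158 without GFP+ replicate 1 and −0.638 without GFP+ replicate 2. Of its pairs 2 were lower in GFP+ cells (0.04, −0.83 and −0.31, paired SE 0.25, exact sign-flip p = 0.5). As a percent of the summed values of each library, the family took 14.65, 24.9 and 17.56 in GFP+ replicates 1, 2 and 3. The GFP− replicates had 14.0, 33.24 and 17.09, so by this measure only pair 2 was lower in GFP+ cells. The authors' ratios for this arm, 2.414 (miR-302a), 1.765 (miR-302d), 1.215 (miR-302b) and 1.192 (miR-302c), are given by neither table, whose ratios of means were 0.381, 0.554, 0.554 and 0.597 (chicken) and 1.708, 2.496, 0.557 and 0.835 (human). For miR-367, to which the authors give 1, no ratio is set beside it because neither table had a read in GFP+ cells.

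The make-up of the family also differed in the overexpression GFP+ cells, a measure chosen after the values were seen. Of the hsa-mir-302a, miR-302d and miR-302b reads, the miR-302a and miR-302d hairpins took 19.08% (95% Wilson interval 14.93 to 24.06), 21.62% (14.98 to 30.16) and 25.53% (19.05 to 33.31) in the 3 overexpression GFP+ libraries, a mean of 22.08 ± 3.25%. In overexpression GFP− cells they took 6.57 ± 0.36%, in knockdown GFP+ cells 5.32 ± 0.59% and in knockdown GFP− cells 4.6 ± 0.17%. In both arms the share was higher in every GFP+ than in every GFP− library (4.81% to 5.96% against 4.5% to 4.8% in the knockdown arm). The nearest knockdown libraries cannot be told apart. GFP+ replicate 3 had a 95% Wilson interval of 4.34 to 5.32 and GFP− replicate 1 of 4.64 to 4.96. An exact two-sided permutation test gave p = 0.1 within each arm, the smallest that 3 against 3 allows.

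**Figure D2:**
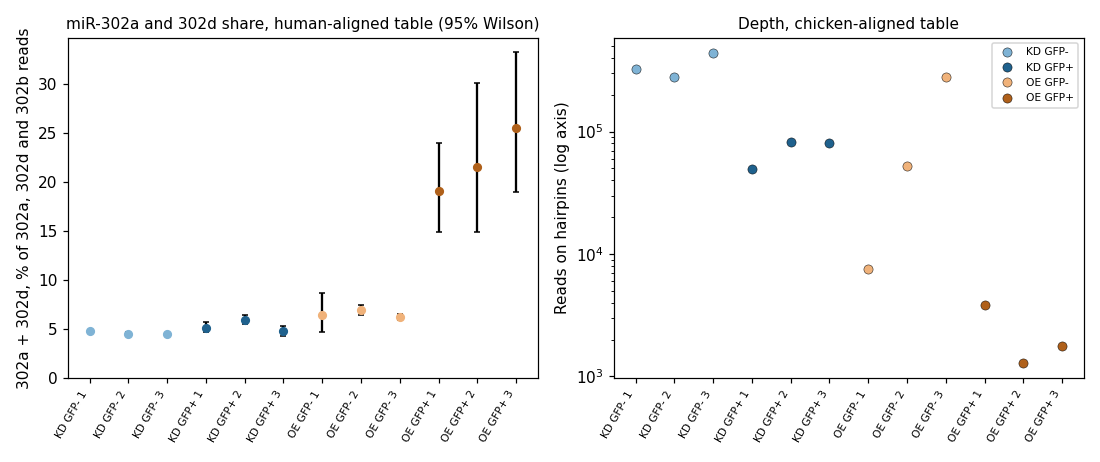
Left, percent of hsa-mir-302a, miR-302d and miR-302b reads that belong to miR-302a and miR-302d in each library, with 95% Wilson intervals as bars; right, reads on hairpins per library of the chicken-aligned table on a logarithmic axis. The 3 overexpression (OE) GFP+ libraries have the highest shares, 19.08% to 25.53% against 4.5% to 6.97% elsewhere, and the fewest reads.

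The second comparison asked which other miRNAs differed between GFP+ and GFP− cells of the knockdown arm. The let-7 hairpins, known for promoting differentiation and rising late in development, were much higher in GFP+ cells: gga-let-7c stood at 546.2 ± 125.3 against 29.1 ± 17.1 (log2 fold 4.31), gga-let-7b at 428.1 ± 54.4 against 24.3 ± 17.3 (4.29) and gga-let-7a-1 at 501.5 ± 108.7 against 60.3 ± 26.0 (3.10). The liver miRNA miR-122 rose with them, gga-mir-122-1 to 2518.1 ± 344.3 from 236.9 ± 163.0 (3.62) and gga-mir-122-2 to 404.7 ± 90.4 from 35.3 ± 27.2 (3.70). gga-mir-375, known from pancreatic islets, had 32.5 against 3.8 (2.73). The 1 falling call was gga-mir-363, of the miR-92 seed family, at 294.9 ± 53.9 against 578.0 ± 61.3 (−0.98). All 3 GFP+ libraries were shallower than each GFP− library.

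Limma called 13 rises and 1 fall among the tested chicken hairpins, edgeR 21 and 4, and DESeq2 23 and 13, and 13 and 14 of the 14 limma calls were shared with each. Limma adjusted p values were 0.000582 (gga-let-7c), 0.00516 (gga-let-7b), 0.00131 (gga-let-7a-1 and gga-let-7j), 0.000956 (gga-mir-122-1), 0.00206 (gga-mir-122-2) and 0.0424 (gga-mir-363). All 14 calls had the 3 GFP+ libraries on one side of the 3 GFP− libraries, as did 63 of all tested hairpins (47.7%, against 10% by chance). The median log2 fold of all hairpins was −0.17, and 0.02 with TMM scaling. The count fell to 9 without GFP+ replicate 1 or 2, 8 without GFP− replicate 2 or GFP+ replicate 3, and 7 without GFP− replicate 3. gga-mir-1732-1 (23.6 ± 8.7 against 1.0 ± 0.3), gga-mir-12249 (10.1 ± 4.1 against 0.6) and gga-mir-375, each with a limma adjusted p of 0.0469, lost the call without any 1 of the 6 libraries (0.0976 to 0.17, 0.0959 to 0.169 and 0.0586 to 0.212). The blocked limma adjusted p was 0.131 for gga-mir-12249 and gga-mir-375, with ranges over the alternatives of 2.46e-05 to 0.728 and 2.27e-05 to 0.467. gga-let-7g (448.8 ± 118.4 against 52.9 ± 22.5, limma adjusted p = 0.00964) lost it without GFP+ replicate 3 (0.055) or GFP− replicate 3 (0.0565). The fall of gga-mir-363 had a limma adjusted p of 0.15 with TMM scaling and 0.0912 with the block (range over the alternatives 0.000995 to 0.381). Its limma adjusted p was 0.139, 0.0801, 0.115, 0.16 and 0.155 without GFP+ replicate 1, GFP− replicates 1 and 2, GFP+ replicate 3 and GFP− replicate 3.

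Of the 10 let-7/miR-98 members in the chicken-aligned table, 8 rose and all 10 did when adjusted over the list alone (fry adjusted p = 0.000636, camera adjusted p = 0.0328 with an estimated correlation). Of the 3 endoderm and liver members, gga-mir-122-1, gga-mir-122-2 and gga-mir-375, 3 rose by either adjustment (fry adjusted p = 0.000371, camera adjusted p = 0.0328 with an estimated correlation). With the block both lists passed fry, but not camera with an estimated correlation (camera adjusted p = 0.181 for both). The miR-17/miR-92/miR-106/miR-25 families fell on balance by fry (adjusted p = 0.0154, camera adjusted p = 0.136 with an estimated correlation), which TMM scaling (0.125) and the block (0.103) ended (range over the alternatives 0.0154 to 0.125), and 1 of 12 members fell by either adjustment. Their most abundant member gga-mir-92-2 had 6048.2 ± 693.9 against 6683.0 ± 964.8 (log2 fold −0.14, and 0.05 with TMM scaling). None of the 13 neural, 3 muscle and cardiac, 3 epithelium, 5 mesenchyme, 2 Hox-cluster or 3 stress and inflammation members was called by limma over all hairpins or over the list alone. Their fry adjusted p were 0.766 (neural), 0.634 (muscle and cardiac), 0.66 (epithelium), 0.634 (mesenchyme) and 0.197 (stress and inflammation, 0.019 with the block, range 0.019 to 0.694, and blocked camera adjusted p = 0.676 with an estimated correlation), and the Hox-cluster list was too short for the test. Some members passed under a few alternatives: gga-mir-1a-1 and gga-mir-1a-2 under 3 of 19 each, and gga-mir-218-1 and gga-mir-218-2 under 2 of 19 each. Values for these groups included gga-mir-128-2 at 179.9 ± 36.3 against 169.9 ± 37.2, gga-mir-1a-1 at 45.2 ± 20.6 against 263.7 ± 125.5, gga-mir-200b at 55.3 ± 28.0 against 55.2 ± 21.7, gga-mir-143 at 87.7 ± 26.9 against 115.4 ± 43.8, gga-mir-10a at 24.8 ± 9.8 against 24.6 ± 21.7 and gga-mir-21 at 1083.8 ± 146.5 against 1265.5 ± 123.4. The single tested member of the blood and endothelium list, the endothelial gga-mir-126, had 48.4 ± 13.6 against 128.7 ± 30.4 (−1.41, limma adjusted p = 0.0751, range over the alternatives 0.000798 to 0.612). It passed limma when adjusted over the list alone or fitted on the compared groups only, and was called by edgeR and DESeq2. No seed relative of miR-302 was abundant enough to test in either table.

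Human hairpins of let-7 and of liver and gut miRNAs were also higher in knockdown GFP+ cells. hsa-let-7c stood at 516.3 ± 88.3 against 26.1 ± 16.8 (log2 fold 4.42), hsa-let-7b at 313.6 ± 19.4 against 16.4 ± 10.9 (4.36) and hsa-let-7a-1 at 386.4 ± 63.9 against 49.5 ± 21.1 (3.01). The liver and gut miRNA hsa-mir-192 had 109.9 ± 7.4 against 9.8 ± 5.2 (3.46), its cluster partner hsa-mir-194-2 50.3 ± 23.1 against 4.2 ± 1.2 (3.25), and hsa-mir-29a, known for repressing collagen genes, 41.5 ± 11.7 against 3.1 ± 0.8 (3.35). Limma called 10 rises and 0 falls among 114 hairpins (25 at an unadjusted p under 0.05), while edgeR and DESeq2 each called 33 rises and 13 falls that included all 10. Limma adjusted p values were 0.000223 (hsa-let-7c), 0.00643 (hsa-let-7b and hsa-let-7a-1) and 0.00305 (hsa-mir-192 and hsa-mir-29a). In 61 hairpins (53.5%, against 10% by chance) the libraries of the groups did not overlap. The median log2 fold was −0.06, or −0.20 with TMM scaling. Of 11 let-7/miR-98 members 7 rose, 9 when adjusted over the list alone (fry adjusted p = 0.000677, camera adjusted p = 0.0776 with an estimated correlation). Of 3 endoderm and liver members 2 rose, 3 over the list alone (fry adjusted p = 0.000677, camera adjusted p = 0.106 with an estimated correlation).

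The other lists held no call in the knockdown arm of the human-aligned table, by limma over all hairpins or over the list alone. Their fry adjusted p were 0.166 (12 members of the miR-17/miR-92/miR-106/miR-25 families), 0.67 (12 neural), 0.612 (3 muscle and cardiac) and 0.166 (3 mesenchyme, 0.0456 with TMM scaling, range 0.0456 to 0.564, and camera adjusted p = 0.426 with an estimated correlation there). The epithelium list with 2 members, Hox-cluster with 1, stress and inflammation with 2 and blood and endothelium with 1 were too short for the test. Some list members passed under a few of 19 alternatives, among them hsa-mir-218-1 and hsa-mir-363 under 5 each and hsa-mir-1-2 under 4. hsa-mir-363 had 348.2 ± 39.9 against 672.8 ± 70.0 (−0.95, limma adjusted p = 0.0747) and hsa-mir-126 65.8 ± 16.5 against 162.5 ± 40.5. hsa-mir-194-2 (limma adjusted p = 0.0158) lost the call without GFP+ replicate 1 (0.0813) or 2 (0.0627) or GFP− replicate 1 (0.0576), 2 (0.0569) or 3 (0.0975), and hsa-let-7i (39.4 ± 17.6 against 5.0 ± 1.3, 0.0113) without GFP+ replicate 2 (0.0508) or GFP− replicate 3 (0.0661). The block gave hsa-let-7i a limma adjusted p of 0.0731 (range 3.29e-06 to 0.464). The count of calls was 6 without GFP+ replicate 2 or without GFP− replicate 3.

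The third comparison asked the same of the overexpression arm. The let-7 and miR-122 hairpins were again higher in GFP+ cells, with gga-let-7b at 210.9 ± 7.3 against 6.4 ± 6.6 (log2 fold 5.52), gga-let-7c at 160.8 ± 71.2 against 15.6 ± 7.3 (3.29), gga-mir-122-1 at 1114.6 ± 614.9 against 79.7 ± 27.9 (3.72) and gga-mir-122-2 at 149.7 ± 44.0 against 12.2 ± 7.9 (3.71). Endothelial gga-mir-126 fell to 43.9 ± 25.5 from 379.4 ± 103.0 (−3.19). The neural hairpins gga-mir-218-2 and gga-mir-218-1, known from motor neurons, fell respectively to 51.5 ± 23.6 from 254.3 ± 28.6 (−2.40) and to 57.4 ± 38.9 from 211.3 ± 10.8 (−2.09). gga-mir-363 fell to 227.1 ± 56.9 from 592.4 ± 119.5 (−1.39), and the smooth muscle miRNA gga-mir-143 to 43.5 ± 31.0 from 158.7 ± 57.3 (−1.99).

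Limma called 12 rises and 13 falls among the tested chicken hairpins, and edgeR and DESeq2 each 13 and 16, with 22 of the 25 shared with each. The falls come from libraries of 1292 to 3856 reads, in which simulated data without any change gave a mean of 2.6 falling limma calls. Limma adjusted p values were 0.00102 (gga-let-7b), 0.00137 (gga-let-7c), 0.000687 (gga-mir-122-1 and gga-mir-126), 0.00145 (gga-mir-122-2), 0.0018 (gga-mir-218-2), 0.00817 (gga-mir-218-1), 0.00352 (gga-mir-363) and 0.0187 (gga-mir-143). Also called were rises of gga-mir-12249 (54.0 ± 49.4 against 3.1 ± 2.3) and gga-mir-1601 (46.1 ± 23.4 against 3.9 ± 3.7), and falls of gga-mir-222a (62.6 ± 35.4 against 236.2 ± 87.7), gga-mir-24 (30.7 ± 14.8 against 111.9 ± 37.2) and gga-mir-146c (120.2 ± 39.2 against 254.1 ± 44.5). Both of these rises rest on few reads. In GFP+ replicates 1 to 3 gga-mir-12249 had 4, 1 and 7 reads and gga-mir-1601 5, 3 and 2. In GFP− replicates they had 1, 6 and 4, and 2, 4 and 4. gga-mir-17 had 2 reads in GFP+ cells where 9.2 were expected (ratio 0.217, 95% counting interval 0.0263 to 0.785), and neither it nor gga-mir-301a (8.9 ± 15.4 against 36.0 ± 3.8) was called by edgeR. In 46 hairpins (34.8%, against 10% by chance) the libraries of the groups did not overlap. The median log2 fold of all hairpins was −0.67, or −0.58 with TMM scaling. The count was 42 without GFP+ replicate 1, 15 without GFP− replicate 3, 10 with a fit of the compared groups only and 33 with the block. Without GFP− replicate 3 the limma adjusted p of gga-mir-17 was 0.0531, of gga-mir-24 0.0531, of gga-mir-222a 0.0891, of gga-mir-143 0.0936 and of gga-mir-146c 0.108. Without GFP− replicate 2 the last pair had limma adjusted p of 0.0634 and 0.069. The gga-mir-301a call (limma adjusted p = 0.0351) was lost without GFP− replicate 1 (0.0616), 2 (0.0796) or 3 (0.108) or GFP+ replicate 2 (0.0653) or 3 (0.0859).

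In the chicken-aligned overexpression arm 8 of 10 let-7/miR-98 members rose, 9 when adjusted over the list alone (fry adjusted p = 0.00169, camera adjusted p = 0.0945 with an estimated correlation). Of 3 endoderm and liver members 2 rose, 3 over the list alone (fry adjusted p = 0.000577, camera adjusted p = 0.0945 with an estimated correlation). The miR-17/miR-92/miR-106/miR-25 families fell on balance (2 of 12 called, 4 over the list alone, fry adjusted p = 0.000724, camera adjusted p = 0.363 with an estimated correlation). gga-mir-92-2 had 6002.2 ± 1029.9 against 7310.5 ± 1353.5. Muscle and cardiac members fell on balance (0 of 3 called, 3 over the list alone, fry adjusted p = 0.0203, camera adjusted p = 0.436 with an estimated correlation). They include gga-mir-206, which had no read in GFP+ cells where 1.8 were expected, so that no fold is given. Among them the muscle miRNA gga-mir-1a-1 had 44.3 ± 40.4 against 269.8 ± 235.2, which limma did not call (adjusted p = 0.0686) but called with the block (0.018, range over the alternatives 0.00779 to 0.233) and without GFP+ replicate 1 (0.043) or 3 (0.0228). Epithelium members, which keep cells epithelial, fell on balance (0 of 3 called, 2 over the list alone, fry adjusted p = 0.0452, camera adjusted p = 0.548 with an estimated correlation). gga-mir-200a had 1 read where 4.2 were expected (ratio 0.237, 95% counting interval 0.006 to 1.32), and limma called it only with the block (adjusted p = 0.0427, range 0.00913 to 0.68) or without GFP+ replicate 1 (0.00913). The neural list had 2 falls among 13 by either adjustment, gga-mir-218-1 and gga-mir-218-2 (fry adjusted p = 0.0997, 0.044 with the block, range 0.044 to 0.397, and blocked camera with an estimated correlation gave an adjusted p of 0.958), while gga-mir-128-2 had 139.4 ± 16.2 against 112.1 ± 24.7. The mesenchyme list had 1 fall among 5 by either adjustment (gga-mir-143, fry adjusted p = 0.302). The stress and inflammation list had 1 among 3 by either adjustment (gga-mir-146c, fry adjusted p = 0.119, with the block 0.0169, range 0.00249 to 0.266, and blocked camera adjusted p = 0.958 and upward with an estimated correlation), with a median log2 fold of −0.45 but a mean of 0.03. Blood and endothelium had 1 of 1 (gga-mir-126), and the Hox-cluster list 0 of 2, with gga-mir-10a at 273.8 ± 295.3 against 92.4 ± 76.1.

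Among human hairpins of the overexpression arm, hsa-let-7b stood at 161.2 ± 63.3 against 5.8 ± 6.3 (log2 fold 5.18), hsa-let-7c at 147.7 ± 6.4 against 12.9 ± 6.1 (3.51), hsa-mir-192 at 67.7 ± 11.5 against 6.5 ± 2.7 (3.25) and hsa-mir-194-2 at 33.0 ± 8.1 against 2.2 ± 2.2 (3.70). A single read was worth 7.88, 38.7 and 18.3 normalized reads in GFP+ replicates 1 to 3. Low GFP+ levels such as the 33.0 of hsa-mir-194-2 therefore rest on few reads, and their folds are uncertain. hsa-mir-126 fell to 69.9 ± 78.4 from 491.2 ± 97.3, hsa-mir-218-1 to 48.7 ± 19.3 from 204.5 ± 4.1 (−2.11) and hsa-mir-363 to 249.4 ± 94.1 from 676.5 ± 105.0. hsa-mir-24-2 fell to 33.0 ± 8.1 from 125.9 ± 45.2 (−1.86), hsa-mir-222 to 43.5 ± 10.2 from 181.4 ± 88.4 (−1.94) and hsa-mir-143 to 86.0 ± 20.9 from 226.1 ± 75.4 (−1.35). The muscle miRNA hsa-mir-1-1 had 3 reads where 20.3 were expected (ratio 0.148, 95% counting interval 0.0305 to 0.432) and hsa-mir-20a 2 reads (ratio 0.2, 0.0242 to 0.721). Limma called 8 rises and 13 falls among 114 hairpins, edgeR 14 and 13 (16 of the 21 shared), and DESeq2 18 and 13 (17 shared), while simulated data without change gave a mean of 4.12 falling limma calls. A limma fit of the compared groups only left 0 calls, no filter left 8 and the block 17. Limma adjusted p values were 0.00334 (hsa-let-7b and hsa-mir-218-1), 0.00205 (hsa-let-7c), 0.00348 (hsa-mir-192), 0.00754 (hsa-mir-194-2), 0.043 (hsa-mir-126), 0.00463 (hsa-mir-363), 0.00778 (hsa-mir-24-2), 0.0192 (hsa-mir-222), 0.0404 (hsa-mir-143), 0.0245 (hsa-mir-1-1) and 0.0458 (hsa-mir-20a). Called too were hsa-mir-4492 (39.9 ± 32.7 against 0.7 ± 0.9), hsa-mir-20b (13.1 against 67.9), hsa-mir-218-2 (40.2 against 225.6), and hsa-mir-146a and hsa-let-7i, which had no read in GFP+ cells where 2.6 and 0.5 were expected, so that no fold is given. In 32 hairpins (28.1%, against 10% by chance) the libraries of the groups did not overlap. The median log2 fold was −0.47, or −0.50 with TMM scaling.

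Of the 11 let-7/miR-98 members in this contrast 5 rose, 6 over the list alone (fry adjusted p = 0.0146, camera adjusted p = 0.236 with an estimated correlation), and with hsa-let-7i left out the median log2 fold was 2.11 instead of 1.85. The falling call of hsa-let-7i, with no read where 0.5 were expected, does not show a lower level. The block ended this fry call (adjusted p = 0.055, range over the alternatives 0.0115 to 0.055). Of 3 endoderm and liver members 2 rose by either adjustment (fry adjusted p = 0.00503, camera adjusted p = 0.236 with an estimated correlation). Falls on balance were found for the miR-17/miR-92/miR-106/miR-25 families (3 of 12 by either adjustment, fry adjusted p = 0.0176, camera adjusted p = 0.377 with an estimated correlation) and for muscle and cardiac members (1 of 3, 3 over the list alone, fry adjusted p = 0.0116, camera adjusted p = 0.318 with an estimated correlation). The block ended both fry calls (adjusted p = 0.055 each, ranges 0.0115 to 0.055 and 0.00435 to 0.055). The muscle list includes hsa-mir-206, which had no read in GFP+ cells where 1.6 were expected, so that no fold is given. hsa-mir-1-2 had 37.6 ± 36.7 against 186.1 ± 165.4. Mesenchyme members also fell on balance (1 of 3, 2 over the list alone, fry adjusted p = 0.00503, camera adjusted p = 0.377 with an estimated correlation). The neural list had 2 falls among 12, 1 over the list alone (hsa-mir-218-1 and hsa-mir-218-2, fry adjusted p = 0.337), blood and endothelium 1 of 1 (hsa-mir-126), stress and inflammation 1 of 2 (hsa-mir-146a, without a read), and epithelium (2 members) and Hox-cluster (1) none. The count of calls was 37 without GFP+ replicate 2 and 10 without GFP− replicate 3. Without GFP− replicate 3 the limma adjusted p was 0.132 for hsa-mir-126, 0.124 for hsa-mir-1-1, 0.139 for hsa-mir-20a, 0.12 for hsa-mir-222, 0.0528 for hsa-mir-24-2 and 0.144 for hsa-mir-143. Without GFP− replicate 2 it was 0.0806, 0.0555 and 0.0974 for hsa-mir-126, hsa-mir-1-1 and hsa-mir-20a and 0.0974 for hsa-mir-143. Without GFP− replicate 1 the limma adjusted p was 0.116 for hsa-mir-126 and 0.104 for hsa-mir-20a, and without GFP+ replicate 1 it was 0.0654 for hsa-mir-143 (limma adjusted p). The calls of hsa-mir-20b and hsa-mir-218-2 were lost without GFP− replicate 1 (0.0993 and 0.116), 2 (0.0616 and 0.0974) or 3 (0.124 and 0.139) and that of hsa-mir-20b without GFP+ replicate 3 (0.0649). The call of hsa-let-7i was lost without any 1 of the 6 libraries (limma adjusted p 0.052 to 0.139). With the block the limma adjusted p was 0.0563 for hsa-mir-1-1 (range 0.000945 to 0.396), hsa-mir-126 (6.19e-07 to 0.197) and hsa-mir-218-2 (0.000492 to 0.263). It was 0.0578 for hsa-mir-20a (0.00949 to 0.383) and 0.132 for hsa-let-7i (0.0172 to 1).

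**Figure D3:**
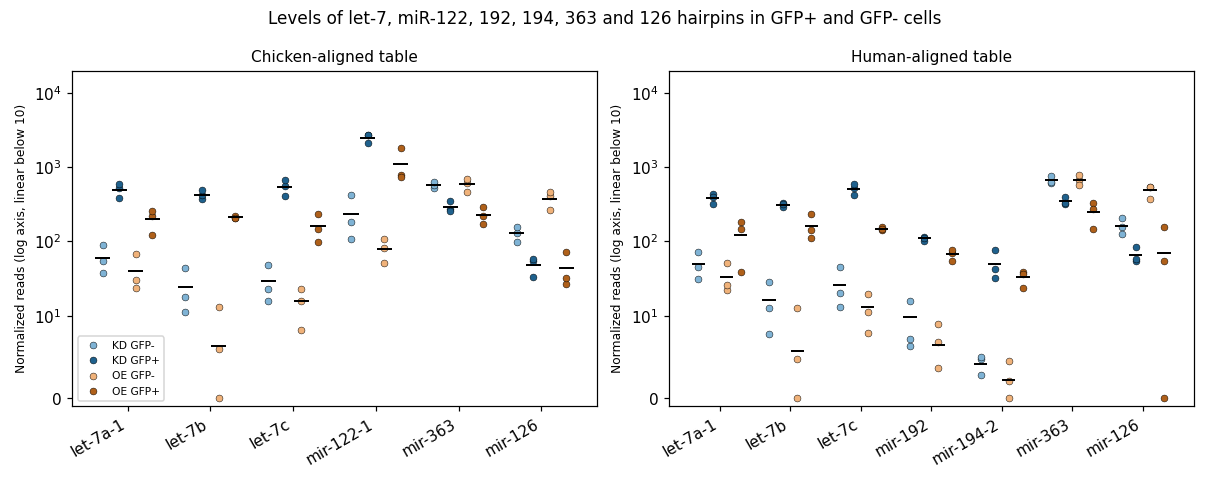
Normalized reads (vertical axis, logarithmic above 10 and linear below) of let-7, miR-122, miR-192, miR-194, miR-363 and miR-126 hairpins, with 1 point per library, a line at the mean of 3 libraries, and colours for the knockdown (KD) and overexpression (OE) groups. gga-let-7b is higher in GFP+ cells of the knockdown arm (428.1 against 24.3) and of the overexpression arm (210.9 against 6.4), and gga-mir-363 is lower (294.9 against 578.0 and 227.1 against 592.4).

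The fourth comparison asked whether GFP+ cells of the 2 arms differed from their GFP− cells in different ways. The summed family had lower means in GFP+ cells of both arms, with ratios of 0.792 and 0.76 (knockdown, chicken and human) and 0.51 and 0.702 (overexpression). Among chicken hairpins, 10 rose in both arms, among them gga-let-7b, gga-let-7c, gga-mir-122-1 and gga-mir-122-2, where 1.18 were expected by chance (Fisher's exact p = 5.78e-11), and gga-mir-363 fell in both (0.1 expected, Fisher's exact p = 0.0985). Among human hairpins, 7 rose in both, among them hsa-let-7b, hsa-let-7c, hsa-mir-192 and hsa-mir-194-2 (0.7 expected, Fisher's exact p = 2.28e-08), and 0 fell. Fisher's test treats hairpins as independent, but near-identical copies such as those of let-7a can share reads. These Fisher p values may therefore be far too small. The difference of the 2 GFP effects was 0.10 on the log2 scale for gga-mir-122-1 (95% interval −1.45 to 1.65) and −1.01 for gga-let-7c (−2.64 to 0.62), so differences of several-fold are not excluded. Across hairpins, which are not independent replicates, the log2 folds of the 2 arms correlated at Pearson 0.77 and Spearman 0.67 (chicken) and 0.66 and 0.64 (human).

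In the chicken-aligned table limma called 0 differences between the arms (9 at an unadjusted p under 0.05), as did edgeR and DESeq2, and the smallest limma adjusted p was 0.0558 (gga-mir-367). Leaving out overexpression GFP+ replicate 1 gave 6 calls and GFP+ replicate 2 gave 1. In the human-aligned table limma called 3, hsa-let-7i, hsa-mir-29a and hsa-mir-146a, while edgeR and DESeq2 called 0. Each had no read in overexpression GFP+ cells, where 0.5, 0.2 and 2.6 were expected from the GFP− level. Reads expected from a rise as in the knockdown arm were not computed. No level below that of GFP− cells is thus shown for these hairpins, and no fold is given. Their limma adjusted p were 0.0118, 0.0118 and 0.0443, and 0 calls were left without overexpression GFP− replicate 3, 6 without overexpression GFP+ replicate 1. The block left 0 calls (limma adjusted p = 0.105, 0.105 and 0.201). Among the leave-one-out fits the first pair lost the call only without that GFP− library (limma adjusted p = 0.0544 for both), and hsa-mir-146a also without any 1 of the knockdown libraries, overexpression GFP− replicate 2 or GFP+ replicate 3 (0.0695 to 0.169). The let-7/miR-98, miR-302/miR-367 and other lists passed the directional fry test in neither table, while its test for change in either direction gave the human let-7/miR-98 list an adjusted p of 0.0477 (0.134 with the block). The miR-302/miR-367 list did not pass that fry test (adjusted p = 0.0586 in the chicken-aligned and 0.865 in the human-aligned table) but did with the block (0.00142 and 0.00149). The miR-302/miR-367 list had a fry adjusted p of 0.23 in the chicken-aligned table (0.0164 with the block, range 0.0164 to 0.199, camera adjusted p with an estimated correlation 0.898, and 0.917 with the block) and 0.504 in the human-aligned table (camera adjusted p = 0.0228 with the preset and 0.946 with an estimated correlation). The median log2 difference of all hairpins was −0.57 (−0.68 with TMM scaling) and −0.77 (−0.67).

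The fifth comparison set the GFP− cells of the overexpression arm against those of the knockdown arm, which shows how far the untargeted cells of the arms differed. Endothelial gga-mir-126 had 379.4 ± 103.0 in the overexpression and 128.7 ± 30.4 in the knockdown arm (log2 fold 1.54), and hsa-mir-126 had 491.2 ± 97.3 against 162.5 ± 40.5. The hepatic gga-mir-122-1 had 79.7 ± 27.9 against 236.9 ± 163.0 (−1.40), gga-mir-302b 4116.9 ± 2328.4 against 7437.7 ± 1067.3 (−0.99) and gga-mir-302d 3544.4 ± 1854.9 against 6129.4 ± 637.0 (−0.92). These hairpins were chosen after their values were seen, as limma called 0 chicken hairpins (10 at an unadjusted p under 0.05, smallest adjusted p 0.548) and 0 human hairpins (3 at an unadjusted p under 0.05, smallest adjusted p 0.999). edgeR called 0 chicken hairpins and 1 human hairpin, hsa-mir-7974 (41.0 against 1.3). DESeq2 called 7 rises and 1 fall in the chicken-aligned table, among them gga-mir-126 and, falling, gga-mir-122-1, and 2 rises (hsa-mir-126 and hsa-mir-7974) and 1 fall (hsa-let-7g) in the human-aligned table.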

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

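The tests of explanations and of other splits in this part were chosen only after the results were seen, unlike the tests of the difference between arms and the block. The differences between the arms in hsa-let-7i (limma adjusted p = 0.0118), hsa-mir-29a (0.0118) and hsa-mir-146a (0.0443) stood out because the test of the difference itself passed. hsa-let-7i and hsa-mir-29a rose in GFP+ cells of the knockdown arm and hsa-mir-146a had 23.5 against 17.7 normalized reads there, and each was without a read in overexpression GFP+ cells, where 0.5, 0.2 and 2.6 reads were expected from the GFP− level. Reads that few do not show a level below that of GFP− cells, and no fold is given. Reads expected from the knockdown fold were not computed. With replicate number as a block the limma adjusted p were 0.105, 0.105 and 0.201, against ranges over the alternatives of 0.00254 to 0.832, 0.00254 to 0.865 and 0.00444 to 0.916. Without overexpression GFP− replicate 3 the limma adjusted p were 0.0544, 0.0544 and 0.169.

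The let-7, miR-122, miR-192 and miR-194 families were higher in GFP+ cells of both arms, though in the overexpression arm only 9 of 10 chicken and 9 of 11 human let-7/miR-98 members had a log2 fold above 0. Of these families only let-7 was tested in both tables. miR-122 was tested in the chicken-aligned table alone, and miR-192 and miR-194 in the human-aligned table alone. Lower depth of the GFP+ libraries stays open as an explanation in the overexpression arm. Sampling fewer reads leaves the expected share of a hairpin alone. In the knockdown arm these hairpins held 13.3%, 18.63% and 15.94% of the summed chicken values in GFP+ replicates 1 to 3. GFP− replicates held 2.53%, 1.44% and 0.99%. The human values were 11.35%, 14.48% and 12.96% against 2.23%, 1.5% and 1.13%. For the knockdown arm these values argue against lower depth by itself. Overexpression GFP− replicates 1 and 2, with fewer reads than the deepest knockdown GFP+ library, held at most 1.33% (chicken) and 1.43% (human) of their summed values in these hairpins. Knockdown GFP+ libraries held at least 13.3% and 11.35%. This comparison across arms cannot decide, because the families were picked for being lower in GFP− cells of both arms. Both GFP− libraries were also deeper than each overexpression GFP+ library. A first version of this depth test, the median log2 fold after thinning (3.83 against 3.05 unthinned in the chicken knockdown arm), was replaced once seen because thinning leaves expected levels alone and zeros can inflate it. Whether zeros did so here was not tested. An opposite response to loss and gain of miR-302 was not tested by the signs in the 2 arms (opposite in 0 of 11 chicken and 1 of 9 human members called in either arm, the latter hsa-let-7i, without a read in overexpression GFP+ cells), because these families were picked for being higher in both. A single outside source of RNA with a fixed mix stays open too. In the chicken-aligned table the median SD of a member's log2 share of the excess over the 6 pairs was 0.45, under a bound of 0.5, for the 11 of 12 members above the GFP− level in every pair. In the human-aligned table it was 0.48, but only 7 of 13 members could be used, too few to decide. These members had a median of 13 (chicken) and 6 (human) reads in overexpression GFP+ libraries. Also open, and untested, are a low RNA input or a response of electroporated cells that may be common to both constructs.

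The falling calls in overexpression GFP+ cells were weighed against zeros in shallow libraries under a pseudocount of 1. The 10 of 13 chicken and 6 of 13 human calls with at least 1 read in each GFP+ library were set apart for having no zero, so neither that nor edgeR tests them. The effect of few reads, down to 1 in a library, stays open for them. Of these calls 9 of 10 chicken and 6 of 6 human ones also passed edgeR, which made a mean of 0.1 and 0.04 calls in simulated data without change. That simulation used 1 common dispersion for all hairpins of a table, so it does not settle the matter. Of the calls with no read in at least 1 GFP+ library 1 of 3 (95% Wilson interval 6.1% to 79.2%) and 3 of 7 (15.8% to 75%) passed edgeR. For these, zeros cannot be told apart from true falls, since edgeR recovered only 46.4% and 46% of simulated falls of 3 on the log2 scale in this contrast. The bound for this second test, first a fixed share passing edgeR, was replaced after the counts were seen. For all falling calls the overexpression construct itself is a biological explanation that stays open and untested.

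The share of hsa-mir-302a and miR-302d reads was larger in overexpression GFP+ cells. Sampling of few reads is argued against, as the lowest lower Wilson bound of the GFP+ libraries, 14.93%, lay above the highest upper bound of the GFP− libraries of that arm, 8.71%. A fall of miR-302b alone stays open, because its test took libraries of the same number as pairs. In the human-aligned table only replicate 2 of the overexpression arm correlated best with its own number. The 2 hairpins were also picked after their values were seen. Relative to reads outside the family, miR-302a and miR-302d reads in these pairs were 3.05 (95% counting interval 2.01 to 4.61), 1.96 (1.29 to 2.99) and 3.93 (2.81 to 5.51) times as high in GFP+ as in GFP− cells. The mean log2 ratio was 1.52 (95% interval over the 3 pairs 0.26 to 2.78), against −0.4 (−1.14 to 0.35) in the knockdown arm. This paired test replaced one on unpaired libraries, whose values per 1000 reads outside the family overlapped (at least 28.51 in GFP+, up to 31.44 in GFP− libraries). A gain from the human construct may be the source, as may a fall of hairpins outside the family, and neither was tested further.

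Other splits of the same libraries were counted for each limma test, and the 10 splits of 3 against 3 are too few for a share under 0.05. In the chicken-aligned table the real split gave 14 calls in the knockdown arm (highest other 0, 1 split with as many) and 25 in the overexpression arm (highest other 5, 1 split), and the difference of effects and the GFP− contrast gave 0 (highest other 0, 10 splits each). Among the 4 splits that part all 3 same-number pairs, the highest other count was 0 in both arms, and the 5 came from a split that parts 1 pair. In the human-aligned table the counts were 10 (highest other 0), 21 (highest other 2) and 3 (highest other 0), each reached by 1 split, and 0 in the GFP− contrast (highest other 0, 10 splits).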

How the results depend on the processing

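Thinning to the shallowest library and the pseudocount worth 1 read there were the alternatives chosen only after the results were seen. Of the 67 calls among 168 named hairpins and comparisons, 22 kept their direction and call under every alternative chosen before the results, and 34 did with all libraries in. Of 3156 alternatives for named hairpins 2676 kept direction and side of the threshold, 274 lost and 82 gained the call, 121 moved without a test and 3 reversed: hsa-mir-146a (thinned, 0.00) and hsa-let-7i (DESeq2, 0.46, and thinned, 0.00) in the overexpression arm, both without a read in GFP+ cells. For comparisons 179 of 228 alternatives were unchanged, and for lists 131 were, with 5 weaker, 6 stronger and 2 moved. In the chicken-aligned table, the 14 knockdown calls became 39 with the compared groups only, 25 by edgeR, 36 by DESeq2, 3 thinned, and 7 to 10 leaving out 1 library (7 without knockdown GFP− replicate 3). The 25 overexpression calls became 10 with the compared groups only, 6.5 thinned (median of 20 draws) and 15 (without GFP− replicate 3) to 42 (without GFP+ replicate 1). The 0 differences of effects became 1 with a pseudocount of 0.5, 1 without the trend and 0 to 6 leaving out 1 library (6 without overexpression GFP+ replicate 1), and the 0 GFP− calls became 8 by DESeq2 and stayed 0 to 0 leaving out 1 library. In the human-aligned table, the 10 knockdown calls became 19 with the 1-read pseudocount, 6 at a minimum mean of 50, 44 with the compared groups only, 46 by edgeR, 46 by DESeq2, 2 thinned, and 6 (without GFP+ replicate 2 or GFP− replicate 3) to 9. The 21 overexpression calls became 8 with no filter, 0 with the compared groups only (edgeR made 14 rising and 13 falling calls, and 36 hairpins had an unadjusted p under 0.05 in limma with all 12 libraries), 1 thinned, and 10 (without GFP− replicate 3) to 37 (without GFP+ replicate 2). The 3 differences became 1 with the 1-read pseudocount, 0 with no filter, a minimum mean of 50, the block, edgeR, DESeq2 or thinning, and 0 (without overexpression GFP− replicate 3) to 6 (without GFP+ replicate 1). The 0 GFP− calls became 1 with the compared groups only, 1 by edgeR and 3 by DESeq2, and 0 to 0 leaving out 1 library. Lists passing camera became 0 with an estimated correlation from 2 (chicken overexpression), 3 (human knockdown), 2 (human overexpression) and 1 (human difference), and lists passing fry with the replicate block became 1 from 0 (chicken difference) and 2 from 5 (human overexpression). The summed miR-302/miR-367 log2 difference ranged leaving out 1 library from −0.457 to −0.162 (chicken knockdown), −1.281 to −0.514 (chicken overexpression), −0.609 to −0.269 (human knockdown) and −0.775 to 0.136 (human overexpression), and with TMM scaling was −0.162, −0.821, −0.554 and −0.400. Pairing the libraries by number gave exact sign-flip p of 0.25, 0.25, 0.25 and 0.5, of which 0.25 is the smallest 3 pairs allow. With the block the call counts were 11, 33 and 0 (chicken) and 9, 17 and 0 (human) for the knockdown, overexpression and difference contrasts, and the GFP− contrast could not be estimated with it. For all these changes the cause was not tested. Comparing 3p arms was not run, as no mature arm was above 0. Depth limits the overexpression GFP+ libraries most, where 3 reads made up 0.078% to 0.232% of the chicken-aligned total.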

Other observations

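The rule fixed before the files were opened named all hairpins in this part except gga-mir-2954 and hsa-mir-122, and all were placed here after their values were seen. gga-mir-2954, a hairpin of the Z chromosome that is known to be higher in male than in female birds, varied between same-number pairs more than between GFP+ and GFP− cells. In the knockdown arm its level was 227 in GFP+ and 230 in GFP− cells of pair 2, and 1499 and 1753 in pair 1 and 1638 and 1421 in pair 3. In the overexpression arm pair 1 had 154 and 156, pair 2 877 and 1026, and pair 3 936 and 1442.

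The hypoxia-linked gga-mir-210a had 80.8 ± 77.9 normalized reads in overexpression GFP+ against 21.6 ± 13.3 in GFP− cells, and 13.1 ± 11.0 against 22.3 ± 3.9 in the knockdown arm, and was not called by limma in either arm. gga-mir-10b had 102.8 ± 164.5 against 35.8 ± 31.2 (n = 3) in the overexpression arm, and the cartilage miRNA gga-mir-140 70.9 ± 9.8 against 94.5 ± 28.7. hsa-mir-122 was listed at 0, while gga-mir-122-1 was among the 10 most abundant chicken hairpins.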
